A study of Mus musculus with 9 samples.

How the data were processed

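Gene expression was measured on 9 Affymetrix Mouse430A 2.0 arrays, 3 for each of 3 sorted CD8+ T cell populations. Per the labels' protocols, naive CD44-low CD62L-high cells were pooled from 2 normal female mice for each preparation. Effector cells, which the labels name effector memory T cells, were CD44-high and CD62L-low, and postmitotic cells were CD44-low and CD62L-high. Both were sorted from 4 pooled male recipients for each preparation, 14 days after irradiation with 10 Gy and transplantation. The transplant held donor naive CD8+ T cells with T cell-depleted marrow. The labels call the 3 arrays of a group biological replicates. Per the labels' protocols, 600 ng of RNA per sample went through 2 rounds of reverse transcription and in vitro transcription before hybridisation.

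Per the deposited readme, the authors reduced the scanner files to trimmed-mean signals per probe set, quantile-normalized these to the array of naive replicate 2, and took log2 after adding an offset of 50 inside a maximum with 0 and 50 outside it. The deposited log2 values therefore cannot fall below 5.64, and a probe set with zero signal has the log2 value 6.64. Folds on this scale understate the changes of dim genes, and a log2 difference from a group mean at or below zero signal is approximate. After that normalization the deposited log2 values have nearly the same distribution on every array, with a median of 7.90 on each, so a change in the total RNA per cell would leave no trace. The share of probe sets at or below zero signal lay between 15.3% and 15.9% per array. The authors' deposited fold columns are ratios made from differences of group means, and their deposited p-values are pairwise contrasts without adjustment for multiple tests, per the readme. Further columns hold the authors' signed score for the probe sets they selected at p under 0.01 and a fold over 1.5; the readme gives 1 and the file holds 0 for those not selected. The series matrix held the same log2 values as the deposited table, with a largest difference of 5e-09. The software version behind the signals is not given in the sources used here, and scanner files were not analysed here.

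Gene symbols came from the annotation deposited with the table and were updated through Entrez numbers in a RefSeq gene table of mouse assembly GRCm38.p6. Of 22690 probe sets, 64 were controls, 21259 named 1 gene, 826 named several and 541 named none. Among those with 1 gene, 20752 matched the RefSeq table and 507 kept the deposited symbol. Probe sets naming several genes or none entered no gene-level test, which left Cd8a without a value. Where a gene had several probe sets, as 5088 genes had, the one with the highest mean over all 9 arrays stood for it, giving 13152 genes. Immunoglobulin, T cell receptor and haemoglobin probe sets can also bind near-identical copies.

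All comparisons used limma (lmFit and eBayes) on the log2 values of all 9 arrays with a mean per group and no covariate, with 6 residual and 2.14 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 13152 genes and called at an adjusted p under 0.05. A moderated F test covered the 3 groups at once. A gene counted as apart in postmitotic cells when it passed against both other groups in 1 direction. The position of each array was its projection on the line from the naive mean (0) to the effector mean (1) over the genes that passed between those groups. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over 29 lists and 87 tests adjusted together, and again with an estimated correlation. For each list, members were counted after adjustment over all genes and adjusted over the list alone. The lists covered naive and memory maintenance, cytotoxic effector molecules, effector transcription factors, inhibitory receptors and exhaustion, cell cycle, quiescence and cell cycle inhibitors, memory stem cell surface markers, interferon-stimulated genes, glycolysis, mitochondrial respiration, fatty acid oxidation, cholesterol synthesis, ribosome biogenesis and MYC targets, pro-survival and pro-death apoptosis genes, homing and chemokine receptors, T cell receptor signalling and costimulation, cytokine receptors and signalling, chromatin and self-renewal regulators, and immediate early and heat shock genes. Further lists held markers of B and plasma cells, myeloid cells, dendritic cells with class II genes, erythroid and megakaryocytic cells, NK cells, CD4 and regulatory T cells, immature thymocytes, gamma-delta and innate-like T cells, and male recipient cells. Of 630 distinct list genes measured, 36 stood in more than 1 list.

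The comparisons, their tests, the lists, the alternatives named below and the rule for named genes were fixed before the data were examined. Chosen after seeing the data were a pair of further alternatives, leaving out both arrays with Y-linked signal and the authors' own criteria, and those tests of explanations that the closing section names as such. The rule named, for each comparison, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap, up to 3 called members of each list or the 1 with the smallest p where none was called, the sort markers, Ly6a, Il2rb, Bcl2, Il7r and Cxcr3, Xist and 4 Y-linked genes, and the 10 highest and 10 lowest genes apart in postmitotic cells. Clone and model names were left out. Genes outside this rule are marked in the text as picked after their values were seen. A gene at or below zero signal on all 3 arrays of a group has only a bound there, and its fold is then given as at least the bright group's mean over the higher of zero signal and the measured value. Cd44 and CD8 were used to sort the cells, so their values only check the labels.

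The alternatives were the series matrix, the mean of all probe sets of a gene, every probe set as its own feature, removal of the dimmest 40% of genes, raising values below the 40th percentile (log2 7.45) to it, a further quantile normalization, a variance prior with trend and robust, array weights, the replicate number as a block, only the 6 arrays compared, stricter thresholds, and refits without each replicate in turn. The fit was tested on simulated arrays of 13152 genes with known changes. For effector minus naive, 11.9% of 67 genes changed by 0.5 log2, 53.7% of 67 changed by 1 and 98.5% of 66 changed by 2 were recovered, with 2 false calls. For postmitotic minus naive the shares were 11.9%, 65.7% and 97% with 5 false calls, and for postmitotic minus effector 14.9%, 68.7% and 98.5% with 19. A planted list of 30 genes shifted by 0.5 log2 in postmitotic cells was called, and a planted position of 0.3 came back as 0.314. The simulated noise was independent between genes, whereas the cell cycle list had an estimated correlation of 0.305. The planted list therefore does not show how camera at the preset correlation behaves on correlated lists. With 3 arrays per group, their number limits the precision of every value. Computations ran in R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.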

Results

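The series compared 3 populations of donor-type CD8+ T cells around graft-versus-host disease (GVHD), in which transplanted T cells attack the tissues of the recipient. Naive cells came from healthy mice, and effector and postmitotic cells were recovered from irradiated, transplanted recipients on day 14. Postmitotic cells carried the same CD44-low CD62L-high surface phenotype as naive cells but came from the diseased recipients. Each group had 3 arrays from separate pools of mice, and the design asks what sets each population apart and where the postmitotic cells lie between naive and effector cells.

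The arrays grouped by cell type. Correlations between arrays of a group lay between 0.976 and 0.986 across genes, and the first principal component, with 55.1% of the variance, separated effector cells from the other two groups. The second component held 13.5% of the variance and placed the postmitotic arrays apart from the naive arrays. The third component (6.6%) set postmitotic replicate 3 (score -27.54) apart from postmitotic replicates 1 and 2 (17.67 and 15.91). The sort marker Cd44 followed the labels and averaged log2 7.28 ± 0.33 in naive, 11.11 ± 0.20 in effector and 7.33 ± 0.40 in postmitotic cells (SD, n = 3). Cd8b1, a chain of CD8, had means of 11.18, 10.91 and 11.53. Other probe sets of Cd8b1 gave calls in the opposite direction, so no order is drawn from it. Donor mice were female and recipients male, and Y-linked transcripts were seen on 2 of the 9 arrays. Eif2s3y, a Y-linked translation factor gene, reached log2 11.47 on postmitotic replicate 3 and 9.50 on effector replicate 3, against at most 7.02 on the other 7 arrays. Ddx3y reached 9.61 and 8.25 on the same arrays, and Xist, the RNA of the inactive X chromosome in female cells, lay at 12.07 on postmitotic replicate 3 against 13.01 to 13.28 on the other 8. Of Xist and the 4 Y-linked genes, Uty alone passed a test between groups, in postmitotic minus effector (log2 0.45, adjusted p = 0.0307). It did not pass without effector replicate 1 (0.102), effector replicate 2 (0.0988) or postmitotic replicate 3 (0.0655), nor without both arrays with Y-linked signal (0.0559), with the mean of its probe sets (0.22, 0.429) or with low values raised to the 40th percentile (0.05, 0.501).

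**Figure D1:**
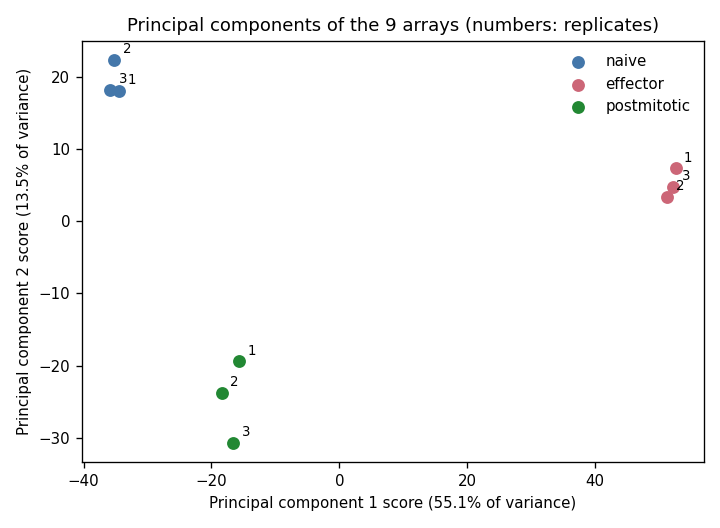
Scores of the 9 arrays on the first 2 principal components (axes in score units, with each component's percent of variance), with 1 point per array coloured by group and numbered by replicate. The first component (55.1%) separates the effector arrays, and the second (13.5%) separates postmitotic from naive arrays.

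**Figure D2:**
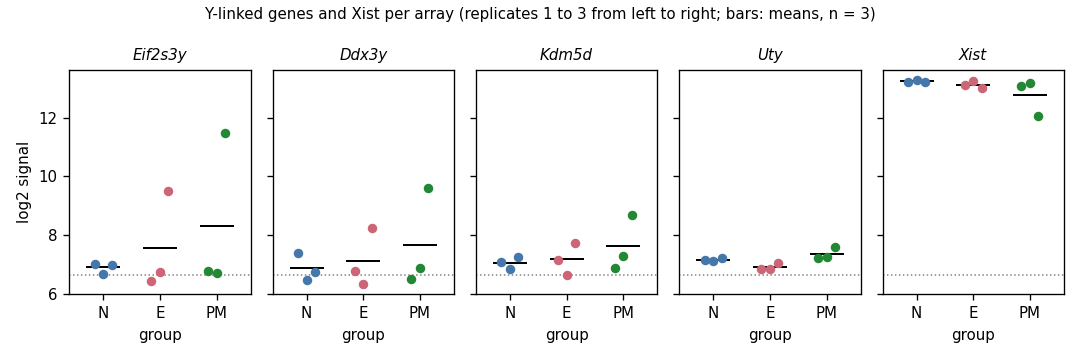
Log2 signal of 4 Y-linked genes and Xist per array, with points for replicates 1 to 3 from left to right, bars for group means (n = 3) and a dotted line at zero signal; N, E and PM stand for naive, effector and postmitotic. Eif2s3y stands at 11.47 on postmitotic replicate 3 and at 9.50 on effector replicate 3, and Xist is lowest on postmitotic replicate 3 (12.07).

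Effector cells were first compared with naive cells, to find what changed in donor CD8+ T cells that took on the CD44-high CD62L-low phenotype in recipients with GVHD. In effector cells 24 of 27 cytotoxic effector genes rose, and 21 of 23 naive and memory maintenance genes fell (camera adjusted p = 4.68e-22 and 1.26e-13). Ccl5, a chemokine of activated T cells, rose from log2 6.76 ± 1.25, near zero signal (6.64), to 15.61 ± 0.08 (SD, n = 3). The log2 rise of Ccl5 was 8.84, with 9.52 without naive replicate 2 and 8.28 without naive replicate 3. Gzmb, a protease of cytotoxic granules, rose from 7.26 ± 0.04 to 15.52 ± 0.10, or 306-fold. Ifng, which encodes interferon gamma, rose from 6.91 ± 0.31 to 14.63 ± 0.02. The calcium-binding protein gene S100a4 (6.13 ± 0.76 to 14.47 ± 0.10) and Pdcd1, which encodes the inhibitory receptor PD-1 (6.38 ± 0.65 to 12.79 ± 0.05), rose from naive means below zero signal. Igfbp4, an insulin-like growth factor binding protein expressed in naive T cells, fell 111-fold, and Ccr7, the receptor that guides T cells into lymph nodes, fell 29.1-fold.

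Of 13152 genes, limma called 4052 (30.8%) between effector and naive cells, 1905 higher and 2147 lower in effector cells, and 748 and 503 of these differed at least 2-fold. The other large rises were those of the granzymes Gzma (log2 7.17) and Gzmk (6.32), S100a6 (6.62), the protease inhibitor Serpina3g (6.61) and the galactose-binding lectin Lgals3 (6.57). Other large falls were those of Tdrp (-4.83), Rflnb (-4.79), the actin-binding calponin Cnn3 (-4.24), Rgcc (-4.22), the interleukin 6 receptor Il6ra (-4.22), Ramp1 (-4.10), a partner of the calcitonin receptor-like receptor, and the ion channel gene Cnga1 (-4.07). Adjusted p-values of these genes lay between 8.55e-08 and 3.58e-05 (limma), with standard errors between 0.087 for Ramp1 and 0.553 for Ccl5. Between the 3' and 5' probe sets of the actin control, log2 signal differed by 1.87, 1.28 and 1.45 on the naive arrays and 0.97, 0.78 and 0.88 on the effector arrays. For the transferrin receptor control it differed by 0.44, 0.38 and 0.54 against 1.41, 1.28 and 1.94. The 5' signal of that control lay below zero signal on the effector arrays (6.58, 6.32 and 5.95), so these differences are approximate. For the Gapdh control the difference was 2.99, 3.03 and 3.12 against 2.88, 2.84 and 2.85. Of the 4052 called genes, 4045 had no overlap between the 3 effector and the 3 naive arrays; over all genes 5938 (45.1%) had none, where chance gives 10%. The authors' deposited table selected 1817 probe sets as higher and 1837 as lower.

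**Figure D3:**
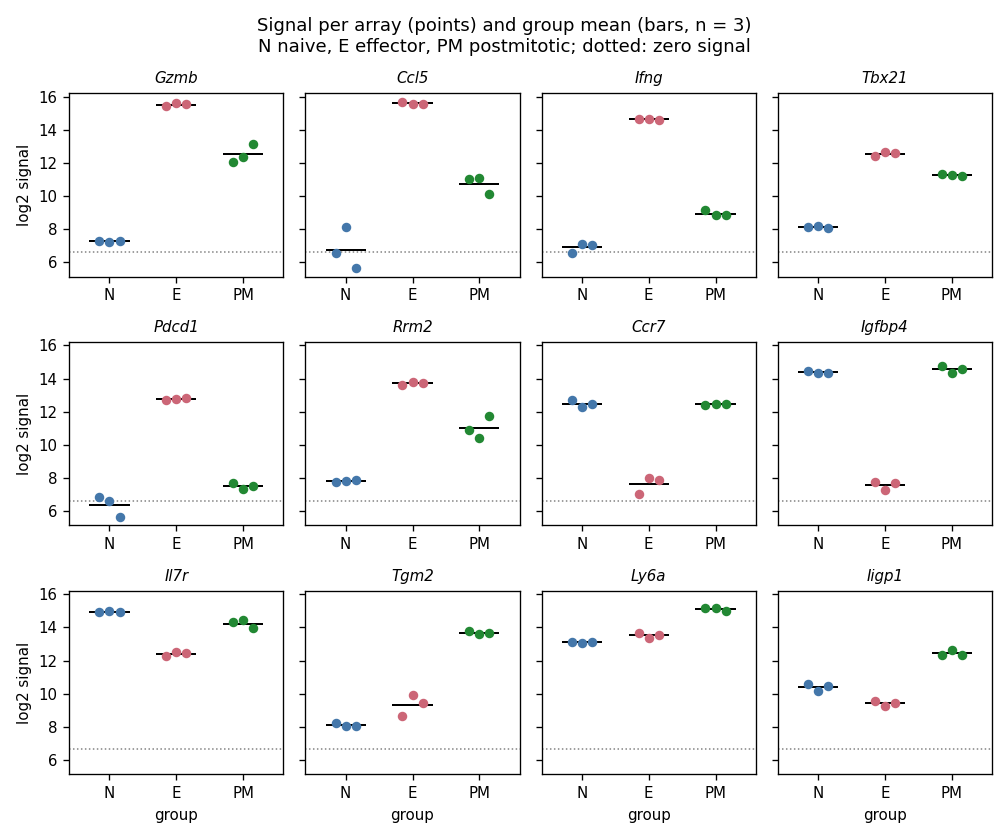
Log2 signal per array (points) and group mean (bars, n = 3) of 12 genes in naive (N), effector (E) and postmitotic (PM) cells, with zero signal dotted. Gzmb and Ccl5 rise in both recipient groups, Ccr7 and Igfbp4 fall in effector cells alone, and Tgm2, Ly6a and Iigp1 are highest in postmitotic cells.

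Genes of T cell effector function rose together in effector cells. Of 27 cytotoxic effector genes, 24 rose and none fell (26 rose adjusted over the list alone), with a median log2 change of 3.92, and the list's shift was called by camera (adjusted p = 4.68e-22). Of 17 effector transcription factors, 15 rose and none fell, the same numbers adjusted over the list alone, among them Tbx21, which encodes T-bet (log2 4.42), and Zbtb32, at least 11.7-fold higher since naive cells lay at zero signal (list adjusted p = 3.03e-13). Bhlhe40 rose from a naive mean of 6.04 ± 0.68, below zero signal (6.64), to 11.63 ± 0.04. Of 14 genes for inhibitory receptors and exhaustion, 13 rose and none fell, all 13 also adjusted over the list alone (adjusted p = 4.79e-13). Pdcd1 was followed there by Havcr2, which encodes TIM-3 (log2 4.73, from a naive mean below zero signal), and the ectoenzyme gene Cd38 (4.53), with Ctla4 at 4.39. Of 23 genes of naive and memory maintenance, 21 fell and 2 rose, also when adjusted over the list alone, with a median of -2.11 (adjusted p = 1.26e-13). Il7r, the interleukin 7 receptor of that list, fell by 2.54. Tcf7 (-2.18) and Lef1 (-2.91), transcription factors of naive and memory T cells picked here after their values were seen, fell as well. Bcl2, an anti-apoptotic gene of the same list, fell by 0.61 (adjusted p = 0.0208). That call was lost without naive replicate 2 (0.0661), effector replicate 2 (0.0502) or effector replicate 3 (0.0788) and with the mean of all its probe sets (-0.04, adjusted p = 0.911).

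Of 42 cell cycle genes, 40 rose in effector cells and none fell, with the same counts adjusted over the list alone. The ribonucleotide reductase subunit Rrm2 (log2 5.91), thymidine kinase Tk1 (5.54, from a naive mean below zero signal) and cyclin B2, Ccnb2 (4.90), were among them. The list's median was 2.59, and its shift (camera adjusted p = 8.64e-30) had adjusted p = 0.0457 with an estimated correlation. Quiescence genes and cell cycle inhibitors went both ways. Of 23, 6 rose, among them Cdkn1a (3.20, from a naive mean of 6.61) and Cdkn2b (2.29), and 12 fell, also over the list alone, with no called shift (adjusted p = 0.253). In glycolysis, 8 of 18 genes rose and 1 fell, with the same counts over the list alone, led by hexokinase 2, Hk2 (2.82), and the enolase Eno3 (2.01; list adjusted p = 0.00047). Of 50 mitochondrial respiration genes, 23 rose and 3 fell (24 and 3 adjusted over the list alone), Sdhb by 0.85 and Fh1 by 0.80. The shift (adjusted p = 6.75e-05) was lost at adjusted p = 0.204 with an estimated correlation. Genes for making ribosomes went the other way. Of 29, none rose and 15 fell, in both adjustments, among them Mybbp1a (-0.92) and Myc (-0.70). The list (adjusted p = 0.00182) had adjusted p = 0.052 with an estimated correlation. Pro-death apoptosis genes rose in 12 of 25 cases and fell in 3 (15 and 4 over the list alone; adjusted p = 0.000153), with Fasl, the Fas ligand (6.05), Casp4 (3.77) and Casp1 (3.28) first. Of 14 pro-survival genes, 4 rose and 2 fell, also over the list alone, and the list was not called (adjusted p = 0.294).

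Interferon-stimulated genes were mixed in effector cells, where 17 of 40 rose and 5 fell (18 and 7 over the list alone). Oas1a, an antiviral 2'-5' oligoadenylate synthetase gene, rose by log2 3.10, Dhx58 by 2.13 and Rsad2 by 1.69, and the shift (adjusted p = 0.00816) was lost at adjusted p = 0.351 with an estimated correlation. Among surface receptors, Cxcr3 (3.06), Tnfrsf9, which encodes 4-1BB (4.66), Il1rl1 (at least 13.9-fold) and the interleukin 2 receptor chain Il2rb (2.65) rose, and the gut-homing receptor Ccr9 (-3.92) fell. The lists of homing and chemokine receptors (14 rose and 10 fell of 33; 15 and 11 over the list alone; adjusted p = 0.178), T cell receptor signalling and costimulation (10 and 5 of 28; 13 and 9; 0.141) and cytokine receptors and signalling (12 and 14 of 37; 13 and 15; 0.987) were not called. Markers of other cells moved with this comparison. Of 32 myeloid markers 5 rose and 1 fell (4 and 0 over the list alone), among them Cd68 (1.76), Cebpb (1.21) and Ly86 (1.14), with adjusted p = 0.0151, and adjusted p = 0.406 with an estimated correlation. Of 15 dendritic and class II markers 4 rose and 2 fell, also over the list alone (adjusted p = 0.304), with H2-Ab1 at 2.19. Of 10 NK cell markers 4 rose, also over the list alone, among them Gzma, Eomes (2.20) and Cd7 (2.05), which CD8+ T cells also make. The list's call (adjusted p = 0.0338) had adjusted p = 0.136 with an estimated correlation and 0.0552 without naive replicate 1.

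Postmitotic cells were then compared with naive cells, which share their sort phenotype, to ask what distinguishes CD44-low CD62L-high cells that had been through the diseased recipient. In postmitotic cells 28 of 40 interferon-stimulated genes and 16 of 27 cytotoxic effector genes rose and none fell (camera adjusted p = 5.02e-23 and 2.85e-10). Tgm2, a protein-crosslinking transglutaminase, rose from log2 8.11 ± 0.10 to 13.68 ± 0.12, or 47.4-fold, and Gzmb rose from 7.26 ± 0.04 to 12.52 ± 0.54, or 38.3-fold (SD, n = 3). Tbx21 rose 8.78-fold and Ly6a, which encodes the stem cell antigen Sca-1, 4.00-fold. Ccl5 rose from 6.76 ± 1.25, near zero signal, to 10.75 ± 0.52, a log2 rise of 3.99 (4.66 without naive replicate 2 and 3.43 without naive replicate 3). Ccr7, picked here after its values were seen, averaged 12.47 ± 0.04 against 12.50 ± 0.18 in naive cells (log2 difference -0.03, SE 0.240, adjusted p = 0.958), and Ccr9 fell 3.86-fold.

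Limma called 1556 genes (11.8%) between postmitotic and naive cells, 806 higher and 750 lower in postmitotic cells, with 188 and 77 at least 2-fold. The count was 849 without naive replicate 3, 901 without postmitotic replicate 2 and 1032 without effector replicate 3. It was 575 with only the 6 arrays compared, and 501 (296 higher and 205 lower) without both arrays that carried Y-linked signal. The variance prior with trend and robust gave 2351. The alternative without both Y-signal arrays was chosen after seeing the data, and without postmitotic replicate 3 alone 1121 genes were called. The other large rises were those of Gadd45g, a growth arrest and stress gene (log2 3.94), Serpina3g (3.92), the membrane semaphorin Sema7a (3.49), the interferon-inducible GTPase Gbp8 (3.26), Rrm2 (3.20) and the kinase Map3k8 (2.93). Falls were smaller: Tsc22d1, a leucine zipper transcription regulator (-2.29), Ccr9 (-1.95), Rgcc (-1.93), the MYC antagonist Mxd4 (-1.85), Gprasp1 (-1.77), the mitochondrial glycerol phosphate dehydrogenase Gpd2 (-1.74), Fhit (-1.72, to a mean below zero signal), Mtss1 (-1.69) and Itgae, which encodes the integrin CD103 (-1.65). Adjusted p-values of these genes lay between 6.02e-05 and 0.00742 (limma). Tacc2 fell by 1.75 (adjusted p = 0.0263), a call lost without naive replicate 1 (0.055), 2 (0.0781) or 3 (0.0713), effector replicate 3 (0.0501) or postmitotic replicate 3 (0.0749). The 3' and 5' signals of the transferrin receptor control differed by log2 1.14, 1.07 and 1.75 on the postmitotic arrays, against 0.44, 0.38 and 0.54 on the naive arrays. The 5' signal of that control lay near zero signal. The actin control differed by 1.48, 1.35 and 1.35 against 1.87, 1.28 and 1.45 in the same order. The Gapdh control differed by 2.89, 2.96 and 2.95 against 2.99, 3.03 and 3.12. Of all genes, 3853 (29.3%) had no overlap between the 3 and 3 arrays, where chance gives 10%, and all 1556 called genes were among them. The authors' deposited table selected 672 probe sets as higher and 545 as lower.

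Interferon-stimulated genes rose together in postmitotic cells. Of 40 measured, 28 rose and none fell (31 rose adjusted over the list alone), with a median of log2 0.79. The shift was called (camera adjusted p = 5.02e-23, and 0.0184 with an estimated correlation). Iigp1, an interferon-inducible GTPase, rose by 2.02, Ly6a by 2.00 and Oas1a by 1.80, and Ifit3 (1.70) and Usp18 (1.66), picked after their values were seen, rose too. The median rise of the list over the naive mean was 0.81, 0.92 and 0.72 on postmitotic replicates 1, 2 and 3, the last of which carried the Y-linked signal. Cytotoxic genes rose in 16 of 27 cases and none fell (17 rose and 1 fell adjusted over the list alone; adjusted p = 2.85e-10), with S100a6 at 2.71 after Gzmb and Ccl5, and medians of 0.82, 0.61 and 0.58 on the same 3 arrays. Of 17 effector transcription factors 7 rose and 1 fell, also over the list alone, led by Tbx21 (3.13). Prdm1, which encodes Blimp-1 and was picked after its values were seen, differed by -0.00 (adjusted p = 0.994). The list's call (adjusted p = 0.0256) had adjusted p = 0.119 with an estimated correlation. Of 14 inhibitory receptor genes 6 rose and 1 fell, also over the list alone, with Cd160 (1.90), Cd38 (1.47) and Ctla4 (1.30), and the list was not called (adjusted p = 0.103).

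Of 42 cell cycle genes, 23 rose in postmitotic cells and none fell (32 rose and 1 fell adjusted over the list alone), with a median of log2 0.82. Rrm2 (3.20), Tk1 (2.47, from a naive mean below zero signal) and the survivin gene Birc5 (2.41) were among them. The shift (adjusted p = 8.11e-16) had adjusted p = 0.127 with an estimated correlation, and the list's median was 0.79, 0.52 and 1.04 on postmitotic replicates 1, 2 and 3, with the Y-linked signal on the third. Of 23 quiescence genes 2 rose and 5 fell (3 and 6 over the list alone), with the antiproliferative genes Btg2 (-1.19) and Tob1 (-1.12) lower (list adjusted p = 0.142). Ribosome biogenesis genes rose in 8 of 29 cases and fell in 1 (15 and 1 over the list alone; adjusted p = 5.91e-07), with Ebna1bp2 at 0.63 (0.44, adjusted p = 0.0511, with the mean of its probe sets). Of 50 mitochondrial respiration genes 6 rose and none fell (13 rose over the list alone), by a median of 0.19, and the shift (adjusted p = 4.82e-07) had adjusted p = 0.133 with an estimated correlation. Of 39 chromatin and self-renewal regulators 3 rose and 9 fell (4 and 14 over the list alone), among them Uhrf1, a reader of DNA methylation that is made in dividing cells (1.53), and the Polycomb cofactor Jarid2 (-1.04). The shift (adjusted p = 0.00511) had adjusted p = 0.0654 with an estimated correlation. Glycolysis (4 rose of 18, also over the list alone; adjusted p = 0.141) and pro-death genes (5 rose and 1 fell of 25; 6 and 1; 0.0639) were not called. The pro-death list was called without naive replicate 2 (0.0271), and its member Pmaip1 rose by 1.27.

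Naive maintenance genes stayed closer to their naive levels than in effector cells: 3 of 23 rose and 8 fell (3 and 10 over the list alone), with a median of -0.24, and the shift (adjusted p = 0.0151) had adjusted p = 0.351 with an estimated correlation. Socs3, a suppressor of cytokine signalling, rose by 1.34 and Bcl2 by 0.97, while Il7r fell by 0.71 (adjusted p = 0.0147; log2 -0.57 and 0.058 without both Y-signal arrays). Of 11 memory stem cell surface markers 4 rose and 2 fell (5 and 2 over the list alone). Cxcr3 rose by 2.03, Ly6a by 2.00 and Bcl2 as above. Il2rb rose by 0.69 (adjusted p = 0.0133; 0.0505 without naive replicate 3 and 0.081 without both Y-signal arrays). The costimulatory receptor gene Cd28 fell by 0.98. The list was called at adjusted p = 0.0429, had adjusted p = 0.208 with an estimated correlation, and was not called without naive replicate 1 (0.0552), naive replicate 3 (0.056) or postmitotic replicate 2 (0.111). Of 14 pro-survival genes 4 rose and 1 fell (6 and 1 over the list alone), with the kinase Pim1 at 1.19. The call (adjusted p = 0.0164) had adjusted p = 0.104 with an estimated correlation and 0.0832 without naive replicate 3. Homing receptors (3 rose and 5 fell of 33; 4 and 6 over the list alone; adjusted p = 0.676), T cell receptor signalling (2 and 4 of 28; 3 and 4; 0.302) and cytokine receptors (11 and 6 of 37; 13 and 8; 0.0758) were not called. Among their members Cxcr6 (-1.64) fell and Tnfrsf9 (1.25) rose. Markers of other cells showed no called list in this comparison: of 16 B cell markers none rose or fell (adjusted p = 0.557), of 32 myeloid markers only Cebpb rose (1.22; 0.747), and of 15 dendritic and class II markers only Ccr9 fell (0.557). The remaining marker lists had adjusted p = 0.937 for erythroid and megakaryocytic cells, 0.294 for NK cells, 0.959 for CD4 and regulatory T cells, 0.438 for immature thymocytes, 0.564 for gamma-delta and innate-like T cells and 0.294 for the Y-linked genes.

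**Figure D4:**
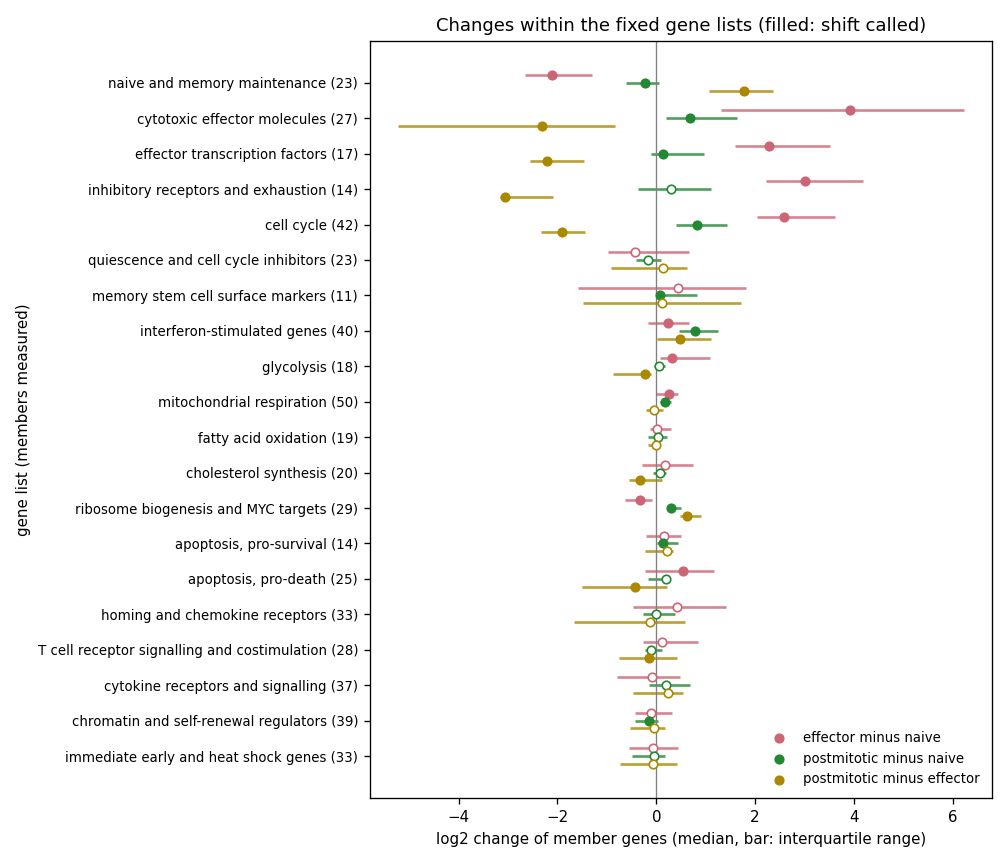
Median log2 change (points) and interquartile range (bars) of the measured members of 20 gene lists in the 3 comparisons; filled points mark lists called by camera at the preset correlation. Across the 3 comparisons, the interferon list has its largest median in postmitotic minus naive (0.79) and the cytotoxic list in effector minus naive (3.92).

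The direct comparison of postmitotic with effector cells asks how far the 2 populations recovered from the same kind of recipient differ. In postmitotic cells 21 of 23 naive and memory maintenance genes were higher and 22 of 27 cytotoxic effector genes lower than in effector cells (camera adjusted p = 6.85e-15 and 2.93e-18). Igfbp4 was 124-fold and Ccr7 28.5-fold higher in postmitotic cells, and S100a4 was 101-fold and Ifng 51.4-fold lower. Fasl had a log2 difference of -5.81. Il7r averaged log2 14.24 ± 0.26 in postmitotic and 12.40 ± 0.11 in effector cells, and Bcl2 10.90 ± 0.28 and 9.31 ± 0.18 (SD, n = 3). Prdm1, a repressor that drives terminal effector differentiation, was 10.7-fold lower, and Klrg1, a receptor of terminal effectors, 40.2-fold lower.

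Limma called 3280 genes (24.9%), 1734 higher and 1546 lower in postmitotic cells, with 401 and 621 at least 2-fold, and 1998 without both Y-signal arrays. Other large falls were those of Lgals3 (-5.73), Ccl4, an inflammatory chemokine (-5.70), Serpine2 (-5.61), Rgs16 (-5.50), Gzma (-5.44), Gzmk (-5.43) and Pdcd1 (-5.28). The postmitotic means of Serpine2 (6.68 ± 0.69) and Rgs16 (6.51 ± 0.90) lay near zero signal (6.64), so the sizes of these falls are approximate. Other large rises were those of Tgm2 (4.35), Il6ra (4.07), Rflnb (3.69), the cannabinoid receptor Cnr2 (3.65, from an effector mean below zero signal), Tdrp (3.38), Ramp1 (3.35) and the sulfotransferase Chst15 (3.29). Adjusted p-values of these genes lay between 2.82e-07 and 6.74e-05 (limma), and 5561 of all genes (42.3%) had no overlap between the 3 and 3 arrays, where chance gives 10%. The 3' and 5' signals of the actin control differed by log2 1.48, 1.35 and 1.35 on the postmitotic arrays and 0.97, 0.78 and 0.88 on the effector arrays. The transferrin receptor control differed by 1.14, 1.07 and 1.75 against 1.41, 1.28 and 1.94 in the same order, with its 5' signal near or below zero signal in both groups. The Gapdh control differed by 2.89, 2.96 and 2.95 against 2.88, 2.84 and 2.85. The authors' deposited table selected 1372 probe sets as higher and 1486 as lower.

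Of the fixed lists, naive maintenance genes were higher in 21 of 23 cases and lower in 2 (adjusted p = 6.85e-15), and cytotoxic genes lower in 22 of 27 and higher in 1 (2.93e-18). Effector transcription factors were lower in 15 of 17 cases (9.72e-14) and inhibitory receptor genes lower in 13 of 14 and higher in 1 (7.96e-13). Each of these lists had the same counts adjusted over the list alone. Of 42 cell cycle genes 37 were lower and none higher (39 over the list alone), among them Tk1 (-3.07), Ccnb2 (-3.04) and Cdk1 (-2.93). The shift (adjusted p = 1.26e-26) had adjusted p = 0.0536 with an estimated correlation.

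Ribosome biogenesis genes were higher in postmitotic than in effector cells in 22 of 29 cases and lower in none (25 over the list alone; adjusted p = 1.03e-10), with Myc (log2 1.30), Nop2 (1.06) and Ppan (1.04). Glycolysis genes were lower in 6 of 18 cases and higher in 1, also over the list alone (adjusted p = 0.000787), with Hk2 (-1.81), Eno3 (-1.98) and Hif1a (-1.53). Pro-death genes were lower in 12 of 25 and higher in 2 (12 and 3 over the list alone; 0.00203), with Fasl as above. Interferon-stimulated genes were higher in 20 of 40 cases and lower in 3 (23 and 7 over the list alone). Iigp1 (3.00), Oasl2 (1.95) and Gbp2 (1.95) were higher, and Oas1a, picked here after its values were seen, was lower (-1.31). That shift (adjusted p = 0.000153) had adjusted p = 0.208 with an estimated correlation. Of 28 T cell receptor signalling and costimulation genes 7 were higher and 12 lower, also over the list alone, with Tnfrsf9 (-3.40), Tnfrsf4, which encodes OX40 (-2.23), and Cd28 (-1.95). The call (adjusted p = 0.0338) had adjusted p = 0.168 with an estimated correlation and 0.06 without effector replicate 2. Myeloid markers were lower in 6 of 32 cases and higher in none (4 over the list alone), with Cd68 at -1.81. Their call (adjusted p = 0.0338) had adjusted p = 0.458 with an estimated correlation, and 0.062 without effector replicate 2 and 0.219 without postmitotic replicate 2. NK markers were lower in 4 of 10 (also over the list alone; adjusted p = 0.0224, and adjusted p = 0.119 with an estimated correlation; 0.0517 without both Y-signal arrays). Dendritic and class II markers were higher in 2 of 15 cases and lower in 3 (2 and 6 over the list alone; 0.197), and this list was called without postmitotic replicate 1 (0.0261). Of the 87 list tests 35 were called at the preset correlation, and 17 held with an estimated correlation, at camera adjusted p = 0.00315 to 0.0457. These were naive maintenance, cytotoxic, transcription factor, inhibitory receptor, glycolysis and pro-death genes in both comparisons of effector with another group, cell cycle in effector minus naive, ribosome biogenesis in both comparisons of postmitotic cells, and cytotoxic and interferon-stimulated genes in postmitotic minus naive. Medians, means and test directions of a list differed in sign in uncalled lists alone. These were memory stem cell markers, cytokine receptors, chromatin regulators, immediate early genes, gamma-delta T cell markers and Y-linked genes in effector minus naive, immediate early genes, NK and myeloid markers in postmitotic minus naive, and quiescence genes and gamma-delta T cell markers in postmitotic minus effector.

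The comparison of all 3 groups asked which genes set postmitotic cells apart from both others and where the cells lie between naive and effector cells. Tgm2, Jun and Gadd45g were highest in postmitotic cells, with log2 differences from naive of 5.57, 2.61 and 3.94 and from effector of 4.35, 3.00 and 2.50. Jun encodes a subunit of the AP-1 transcription factor. The water and solute channel Aqp9 (2.53, from a naive mean below zero signal, and 2.15), Drc1 (2.08 and 2.58), Iigp1 (2.02 and 3.00), Plac8 (1.92 and 2.10), Hemgn, a haematopoietic nuclear protein gene (2.20 and 1.68), the ubiquitin ligase Rnf157 (1.61 and 2.62) and Ly6a (2.00 and 1.58) followed in the same manner. Lower in postmitotic cells than in both other groups were Gpd2 (-1.74 and -3.80), Tacc2 (-1.75 and -3.13), the chemokine receptor Cxcr6 (-1.64 and -3.19), Tsc22d1 (-2.29 and -1.47), the lipid droplet protein gene Plin2 (-1.39 and -1.47), Mxd4 (-1.85 and -1.38) and ceramide kinase, Cerk (-1.51 and -1.31). Among the other genes the rule named, Il18bp was higher (1.77 and 2.00; adjusted p = 0.053 against naive without both Y-signal arrays), and Itga4 was lower (-1.28 and -2.69; 0.0597 against naive with the mean of its probe sets). The call of Tacc2 against naive cells was lost without naive replicate 1, 2 or 3, effector replicate 3 or postmitotic replicate 3 (adjusted p = 0.0501 to 0.0781). Dnajc12 (-1.17 and -2.06) and Nppb (-1.16 and -1.26, to a mean below zero signal) were lower as well. Against naive cells Dnajc12 was not called without naive replicate 1 (0.0788) or 3 (0.0978), effector replicate 1 (0.053), 2 (0.0563) or 3 (0.0582), or postmitotic replicate 2 (0.0569), and Nppb not without naive replicate 3 (0.0629) or postmitotic replicate 1 (0.0552) or 3 (0.056). Nppb was also not called with low values raised to the 40th percentile, against naive (-0.06, 0.833) or effector cells (-0.08, 0.602).

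In all, 412 genes were apart in postmitotic cells, 242 higher and 170 lower than both other groups. The count was 225 without naive replicate 3, 232 without effector replicate 3, 235 without postmitotic replicate 2, 253 without effector replicate 2 and 273 without effector replicate 1. It was 119 without both Y-signal arrays, 663 without the dimmest 40% of genes, and 672 with the trend and robust prior. The F test called 4500 genes (34.2%) among the 3 groups. Along the line from naive (0) to effector (1), over the 4052 genes called between those groups, the postmitotic arrays lay at 0.275, 0.254 and 0.277, with a mean of 0.269 ± 0.013 (SD, n = 3). The position differed between groups of genes, with no test made. Cell cycle genes lay at 0.375 ± 0.088, cytotoxic genes at 0.284 ± 0.008 and effector transcription factors at 0.273 ± 0.030. Inhibitory receptor genes lay at 0.160 ± 0.010 and naive maintenance genes at 0.054 ± 0.010. Only members called in effector minus naive entered, 40 for cell cycle and 24 for cytotoxic genes. These log2 positions are not shares of linear signal. For members raised at least 2-fold, the median linear rise over naive was a smaller part of the effector rise. On postmitotic replicates 1, 2 and 3 it was 13.8%, 6.1% and 15.9% for cell cycle and 3.8%, 1.3% and 2.5% for cytotoxic genes.

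Genes such as Gzmb, Ccl5 and Tbx21 rose over naive cells in both recipient groups, as 502 genes did, and 508 fell in both, against 116.7 and 122.4 for independent lists. Opposite directions were called for 103 genes, 56 of them higher in postmitotic and lower in effector cells, as were Socs3 and Iigp1, picked after their values were seen. A further 443 genes were called in postmitotic minus naive but not in effector minus naive, which is no test of a difference between the recipient groups. Both comparisons share the 3 naive arrays. In 50 simulations of unchanged groups against such arrays, limma called on average 0 genes in both in 1 direction (164.3 at an unadjusted p under 0.05). With no gene changed, adjustment leaves almost no calls, so this 0 is no baseline for the 502 and 508 shared calls. The correlation of the log2 changes across genes, which are not independent replicates, was 0.527 against 0.497 in the simulations, and their covariance was 0.170 against 0.0252. With 3 naive arrays, no split leaves 2 on each side for these overlaps, so part of the excess may come from the shared arrays.

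**Figure D5:**
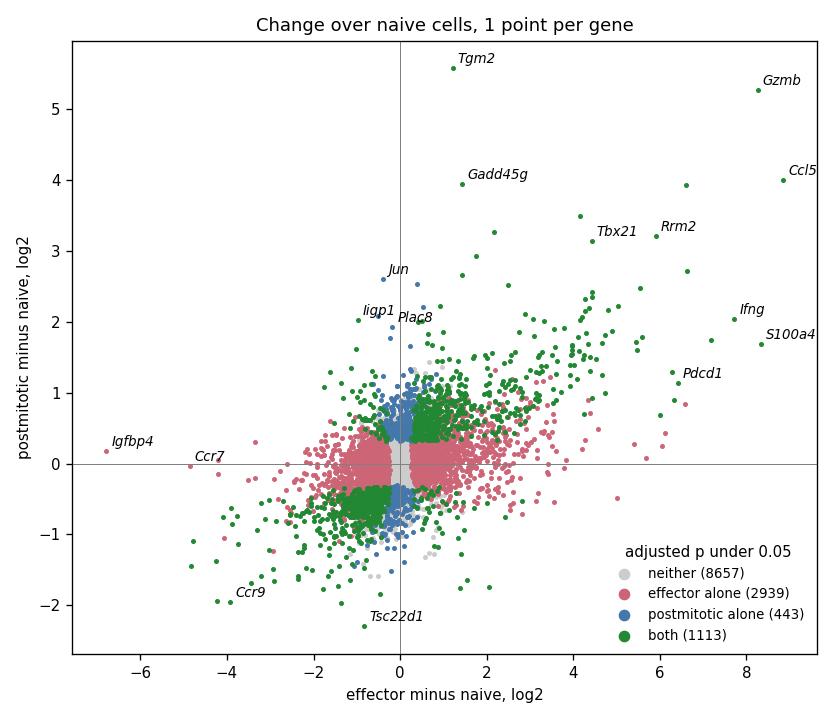
Log2 change over naive cells in effector (x axis) and postmitotic cells (y axis), with 1 point per gene for 13152 genes, coloured by which comparison was called. Gzmb and Ccl5 rise in both, Tgm2 mainly in postmitotic cells (5.57), and Igfbp4 and Ccr7 fall in effector cells alone.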

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

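Both tests in this part were chosen after the result was seen. The labels give female donors, yet Eif2s3y, a gene on the Y chromosome, had a log2 signal of 9.50 on effector replicate 3 and 11.47 on postmitotic replicate 3, above the highest naive array (7.02). The Y-linked genes were named and tested between groups by plan, but the signal stood out on single arrays, which no planned test covered. Ddx3y and Kdm5d were also above the other 7 arrays on both (8.25 and 9.61, and 7.73 and 8.69), and Uty on postmitotic replicate 3 (7.58) but not on effector replicate 3 (7.05).

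Noise of single probe sets is argued against, since 3 of the 3 other Y-linked genes, Ddx3y, Kdm5d and Uty, stood above all of the other 8 arrays on postmitotic replicate 3. Male cells or their RNA in the preparation are a candidate explanation, as Xist lay lower there by a log2 difference of -1.11, at 45.8% of the mean linear signal of the other 8 arrays, which spanned 0.27. On effector replicate 3, Eif2s3y had 22.8% of the linear signal of postmitotic replicate 3, and Xist stood at 13.01, the low end of the other 8 arrays. It stays open whether such cells came from the male recipients, from the transplanted marrow, whose source the labels do not name, or from another sample, and no biological explanation was tested.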

How the results depend on the processing

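The alternatives without both Y-signal arrays and with the authors' criteria were chosen after seeing the data. Where no construction is named below, the cause was not tested. Of 320 results for named genes, 298 passed. Under the refits that left out 1 replicate, 2720 values for named genes kept direction and side of the threshold and 160 no longer passed. Without both Y-signal arrays 278 kept both and 42 no longer passed. With low values raised to the 40th percentile 304 kept both, 14 no longer passed and 2 newly passed. With the mean of all probe sets of a gene, 297 kept both, 22 no longer passed and 1 reversed: Cd8b1 in postmitotic minus effector had -0.066 against 0.618, where other probe sets run the other way. The series matrix gave the same 4052, 1556 and 3280 genes. A further quantile normalization kept 99.2% to 99.4% of the calls.

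Counts moved by over 1.5 times in these cases. Among refits without 1 replicate, postmitotic minus naive had 849 without naive replicate 3, 901 without postmitotic replicate 2 and 1032 without effector replicate 3. Genes apart numbered 225 without naive replicate 3 and 235 without postmitotic replicate 2. They numbered 273, 253 and 232 without effector replicates 1, 2 and 3. Without the dimmest 40% of genes, which lowers the number of genes tested, 663 genes were apart in postmitotic cells. The trend and robust prior gave 2351 genes in postmitotic minus naive and 672 apart. Requiring at least 2-fold, a stricter rule, gave 1251 in effector minus naive, 265 in postmitotic minus naive, 1022 in postmitotic minus effector, 1515 by the F test and 51 apart. An adjusted p under 0.01, stricter also, gave 2687, 509, 2080, 2828 and 117 in that order. Only the 6 arrays compared gave 575 in postmitotic minus naive. Without both Y-signal arrays, a smaller set, there were 501 in postmitotic minus naive, 1998 in postmitotic minus effector and 119 apart. Effector minus naive then had 3105, which is within 1.5 times. The authors' criteria gave 2420, 797 and 1931 genes, fewer than limma in each comparison. Camera with an estimated correlation called 17 of the 87 list shifts. The position of postmitotic arrays, which is no count, was 0.286 over all genes against 0.269 in the main fit.

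With 1 replicate left out, counts ranged from 3133 to 4153 in effector minus naive, 849 to 1461 in postmitotic minus naive, 2440 to 3482 in postmitotic minus effector, 3395 to 4414 by the F test and 225 to 393 apart. The position ranged from 0.260 to 0.283 and called list shifts from 32 to 36. Without the dimmest 40% of genes, lists left with under 3 members gave no value. That filter ended the list calls of myeloid markers in effector minus naive (adjusted p = 0.0803), memory stem cell markers in postmitotic minus naive (0.0805) and cholesterol synthesis in postmitotic minus effector (0.0803). It added immature thymocyte markers in effector minus naive (0.0382) and NK markers in postmitotic minus naive (0.0463). Genes near zero signal have folds compressed by the offset, and 580, 700 and 561 genes lay at or below it on all naive, effector and postmitotic arrays. With the replicate number as a block, the counts were 3830, 1130 and 3039, and called list shifts 32, without memory stem cell markers in postmitotic minus naive (0.0592), and cholesterol synthesis (0.0592) and T cell receptor signalling (0.0671) in postmitotic minus effector. In that block 10 results for named genes no longer passed, among them Tacc2 (0.0506) and Dnajc12 (0.0516) in postmitotic minus naive. Deviations of arrays with the same number in that block correlated at 0.015 to 0.062, all under 0.1. Effector and postmitotic arrays each correlated best with the other's array of their own number (0.061, 0.062 and 0.031). Naive and postmitotic arrays did the same (0.054, 0.042 and 0.025). Among effector arrays, however, naive replicate 3 correlated best with effector replicate 2 (0.018) rather than effector replicate 3 (0.015), so this did not hold throughout. Arrays with different numbers correlated at -0.052 to 0.018, so a small effect shared by arrays of the same number cannot be excluded. The block kept 90.5% of the calls in effector minus naive, 68.6% in postmitotic minus naive and 88.2% in postmitotic minus effector. The labels do not say whether effector and postmitotic preparations share recipients.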

Other observations

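Genes of the immediate early and heat shock list moved in both directions in postmitotic cells. Of 33, 6 rose and 8 fell against naive cells (6 and 10 adjusted over the list alone; adjusted p = 0.371), with Fos (log2 2.01) and Jun (2.61), which form the AP-1 transcription factor, and Ier3 (1.64) higher. Egr2 (-0.96), a transcription factor induced by T cell receptor signals, and the chaperone genes Hsph1 (-1.59) and Dnaja1 (-0.99) were lower; these 3 were picked after their values were seen. Against effector cells 8 were higher and 10 lower (8 and 12 over the list alone; adjusted p = 0.197), among them Nr4a2 (-3.06) and Rgs1 (-1.98). In effector minus naive 8 rose and 8 fell (12 and 8 over the list alone; adjusted p = 0.728).

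Of 20 cholesterol synthesis genes 7 rose and 4 fell in effector minus naive (8 and 4 over the list alone; adjusted p = 0.123), with Fdft1 (1.13) and Idi1 (1.00) higher. In postmitotic minus effector 3 were higher and 7 lower (4 and 11 over the list alone), with a list adjusted p = 0.0456, and adjusted p = 0.192 with an estimated correlation. That call was absent without naive replicate 3 (0.056), effector replicate 2 (0.062), effector replicate 3 (0.0661) or postmitotic replicate 2 (0.0693). Of 19 fatty acid oxidation genes 4 rose and 1 fell in effector minus naive, also over the list alone (adjusted p = 0.34), with the dehydrogenases Acadl at 2.40 and Acadm at -0.86.

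In the following paragraphs, the tests on carry-over, on cell cycle genes and on other cell types were chosen after the results were seen. The other splits of the arrays were planned before. The test of interferon-stimulated genes against male cells was written before its result was seen. Its choice of replicate 3, however, rested on the Y-linked signal already seen on that array. Although the gate was CD44-low and CD62L-high, 23 of 42 cell cycle genes (adjusted p = 0.127 with an estimated correlation) and 16 of 27 cytotoxic genes rose in postmitotic minus naive. Carry-over of effector cells at 1 share for every gene is argued against, because the median share of the effector rise on postmitotic replicates 1, 2 and 3 was 13.8%, 6.1% and 15.9% for cell cycle genes and 3.8%, 1.3% and 2.5% for cytotoxic genes (5.49 times between the medians of these arrays), with 37.9% for Tbx21, 12.8% for Gzmb and 0.5% for S100a4. This rejects only 1 common share, and a small carry-over behind part of the cytotoxic rise cannot be excluded. Mean shares were 3.3% for Ccl5, 1.5% for Gzma and 1.5% for Ifng, but 26.5% for Nkg7 and 82.4% for Klrk1. These genes were picked here after their values were seen. Male cells on postmitotic replicate 3 are argued against as the whole cause, because the lower of the cell cycle medians on replicates 1 and 2 was still log2 0.52 above naive. Division or partial activation of some cells within the gate was not tested and stays open.

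Interferon-stimulated genes were raised in postmitotic cells on all 3 arrays. Male cells on replicate 3 are argued against, because the lower of the list's medians on replicates 1 and 2 was log2 0.81, and carry-over of effector cells is argued against, because 20 members were higher in postmitotic than in effector cells. B, myeloid or dendritic cells are argued against, because the median change of their 5 abundant markers was -0.18, with a largest SE of 0.47. Of 63 measured markers, 1 (Cebpb) was called higher. Irradiation, transplantation, disease and handling of the recipients stay open and untested, since no group had some of these without the others.

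Other splits of the arrays were fitted with limma. The 10 splits of 6 arrays are too few for a share under 0.05, with real values of 4052, 1556 and 3280 genes and 0 as the highest of the others in each comparison (495, 921 and 457 genes at an unadjusted p under 0.05). Of 100 splits drawn from the 280 of all 9 arrays, 1, the real one, reached the 4500 genes of the F test (highest other 2167), the 412 genes apart in postmitotic cells (highest other 10) and the 35 called list shifts (highest other 29). At a share under 0.05 this argues against all 3 groups being alike. Most other splits mixed effector arrays into other groups, which widens the spread within groups. They therefore cannot tell whether the 412 genes set postmitotic cells apart beyond chance, and no conclusion on those genes is drawn from them.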
